A study of Mus musculus with 2 samples.

How the data were processed

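Sap130 is a subunit of the Sin3-HDAC corepressor complex, which removes acetyl groups from histones. Its binding sites were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which crosslinked chromatin is enriched with an antibody and the recovered DNA is sequenced. The material was brain from wild-type mouse embryos on the B6 background at embryonic day 13.5. The labels name 1 library precipitated with 2 µg of a rabbit antibody against Sap130 and 1 library of input DNA, the unenriched chromatin. Per the labels' protocols, chromatin was prepared with a commercial kit for transcription factor ChIP and libraries with a commercial DNA library kit.

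Per the submitters' processing notes, the authors used Bowtie 1.1.2 and MACS2 2.1.0.20140616 with the mouse genome GRCm38 (mm10). The alignment settings, the treatment of reads with several matches, the peak threshold and any filter are not given in the sources used here. The authors deposited 1 table of peaks. For each peak it gives a running number, a chromosome, a start and an end. Most peaks also carry a gene symbol with a RefSeq transcript model (strand, transcript and coding bounds, exons). The table used here has no peak height, fold enrichment, p-value or q-value, and no read totals, so the depth of both libraries is unknown. The quantity by which the list was ordered is not stated. The list is not in genomic order, and width fell along it (Spearman's rho = -0.72 across peaks, which are not independent replicates). The running number is called the place in the list below, with 1 as the first peak.

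The rule by which the authors joined genes to peaks is not stated, so it was read from the values. Each labelled peak carried 1 gene, and its centre lay at most 1000.5 bp from the transcription start of that model. A label was therefore treated as a promoter peak within 1 kb, the window chosen before the data were examined. Transcript starts in the table count from 0 and were raised by 1 base for printing. Peak coordinates are printed as deposited. Of the labelled peaks, 12520 were matched to a RefSeq gene of GRCm38.p6 by transcript accession and 134 by symbol or synonym, while 2 stayed unmatched. The background for gene lists was the 20953 protein-coding genes on the autosomes and X with a curated transcript, since the labels came from curated transcripts. The test had been set out with all protein-coding genes as background and with peak summits. The restriction to curated transcripts was made after the table was examined, the wider background is given as another setting, and peak centres stand in for summits, which the table used here does not give. The reference table gives both ends of each gene but no strand.

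Gene lists were fixed before the data were examined. Older symbols were matched through synonyms. The share of a list's genes with a promoter peak was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 21 lists. Some genes belong to more than 1 list. These tests run across genes of 1 peak list and not across samples. With 1 library of each kind there is no replicate check, and no test of reproducibility was possible. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. For a share of 0, the limit is 3 counts of the total. To judge where peaks lie, all nuclear peaks were placed 100 times at random on their own chromosome, between its first and last annotated gene. The place and width of a list's promoter peaks were set against 10000 random lists of the same size, and against lists matched on deciles of width or place. For a gene with several peaks the earliest in the list was used. The list test was tested on simulated data over 20953 genes. It called 5 of 5 lists planted at a share of 85%, 5 of 5 planted at 10%, and 0 of 10 left at 50%. The simulated genes were drawn independently and the simulated lists shared no genes. The simulation therefore does not cover linked genes, overlapping lists or smaller differences.

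The rule for named genes asked for the highest peaks. Without a height, the place in the list was used in its stead, so the named genes are the study's own genes, the first 20 protein-coding genes in the list, the first 10 distal peaks, and in each gene list the 4 members earliest in the list with up to 3 members that lack a peak. A count of 5 or fewer was named in full. Some genes that this rule would name are not reported here. Genes singled out beyond this rule are marked as chosen after their values were seen, while genes named only as the label or neighbour of a peak are not. Other settings chosen before the data were examined were a window of 500 bp, 1 start per gene (the outermost 5′ end), and peaks without X and the mitochondrial chromosome. Chosen after seeing the data were the first 8115 peaks, the widest 8115 peaks, peaks near either end of a gene, and a background of all protein-coding genes. Stricter thresholds by q-value or fold enrichment were not run for want of those values. The authors' gene column, at first meant as another setting, became the main assignment because the reference has no strand. For the same reason bidirectional promoters and wider windows around starts were not analysed here. No genome sequence was used here, so CpG content and sequence motifs were not analysed. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.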

Results

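The data set describes where Sap130 was found on chromatin of the mouse brain at stage E13.5. It comprises 1 Sap130 ChIP library and 1 input DNA library, both from wild-type brain, and the list of peaks that the authors called from them. The series title places the work in a study of neurodevelopmental and behavioural defects in congenital heart disease. The comparison made by the design is that of Sap130 ChIP with input, and the question is which genes and regions carry Sap130. All values below describe a single peak list, with no replicate and with unknown sequencing depth.

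Sap130 peaks lay mainly at gene starts. The list held 16231 peaks covering 13533.6 kb, with a median width of 690 bp (quartiles 411 and 1082 bp). Of these, 12656 (78.0%, interval 77.3 to 78.6) carried a gene whose transcription start lay within 1 kb of the peak centre, and 3575 carried none. Measured without strand, 70.9% of nuclear peaks had their centre within 1 kb of either end of a RefSeq gene, against 3.69% on average and at most 4.04% in 100 random placements. Peaks outside protein-coding genes and over 1 kb from gene ends made up 5.20%, against 58.1% on average in the random placements. The list contained peaks on all autosomes and X, 5 on the mitochondrial chromosome and 0 on Y.

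The centres of labelled peaks fell just inside the gene. Their median position was 196.5 bp downstream of the start, and 77.3% lay downstream. By the authors' transcript models, 39.8% of the centres were in intron 1, 22.7% upstream of the gene, 18.5% in the 5′ UTR part of exon 1 and 14.7% in its coding part. Labelled peaks were wider than peaks without a gene, with median widths of 761 and 441 bp, although the 3575 unlabelled peaks held a larger share of peaks of 2 kb or more (6.24% against 3.66%).

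**Figure D1:**
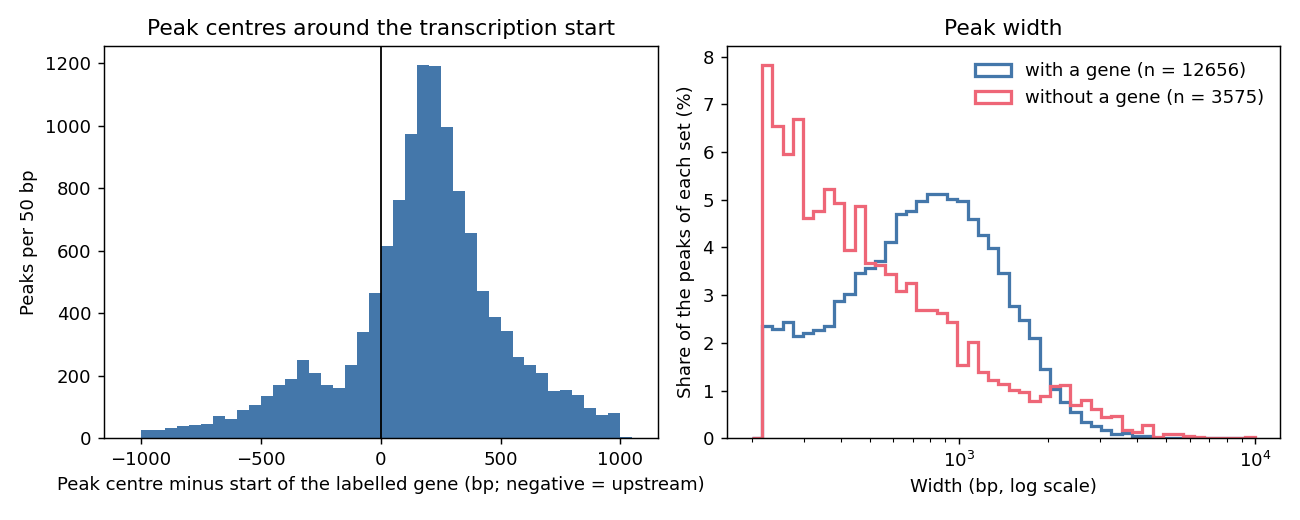
Left, number of labelled peaks per 50 bp by the distance of the peak centre from the transcription start of the labelled gene. Right, width of peaks with a gene (n = 12656) and without one (n = 3575), as a share of each set on a log width axis. Most centres lie downstream of the start (77.3%), and unlabelled peaks are mostly narrower (median 441 against 761 bp).

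At the gene level, 10314 of 20953 protein-coding genes (49.2%, interval 48.5 to 49.9) had a Sap130 promoter peak. The labels also named 321 long non-coding RNA genes and 48 microRNA genes. Most genes had 1 labelled peak, 1556 had 2 and 149 had 3. The 17 genes with 4 or more, from which these examples were chosen after their values were seen, included the neuronal transcription factor gene Myt1l, the chromatin organiser Satb1, Phf21a, a component of a histone demethylase complex, and Tgif1 with 5, a homeobox repressor gene in which mutations cause holoprosencephaly.

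Sap130 occupied its own promoter and those of most of its partners. The Sap130 label stood on 3 peaks around its start on chromosome 18, the earliest in the list being a 546 bp peak at 31634328 to 31634874 in intron 1 (place 1270), with further peaks at 31635068 to 31635593 and 31633764 to 31634208. Of 24 genes of the Sin3-HDAC complex, 20 (83.3%, interval 62.6 to 95.3) had a promoter peak, compared with 49.2% of other genes (Fisher's exact test, adjusted p = 0.0010). The earliest in the list were Arid4a (1339 bp, place 341), Ing1 (2049 bp, place 611), Sap30l (1786 bp, place 820) and Sin3a, the scaffold of the complex (1212 bp, place 850). The 4 genes without a label were Sap18, Kdm5a, Morf4l1 and Ogt. A peak overlapped the 1 kb around an end of each of these 4 genes as well, but it was assigned to another gene (Mir3077 for Sap18, Ccdc77 for Kdm5a) or to none. With a window of 500 bp the share fell to 54.2%, against 44.0% of other genes, and the list was not shown to differ (adjusted exact p = 0.48). Lists outside the complex had higher shares within 1 kb, such as splicing factors (86%) and cell cycle genes (91.3%). A raised share is thus not particular to partners of Sap130, and promoter CpG content was not taken into account.

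The first 20 protein-coding genes were Ncl, Trmt61a, Mettl1, Ddx21, Utp20, Taf4b, Gar1, Fbxo5, Ino80, Psme3, Mat2a, Rrm2, Gpatch4, Ccne2, Nol12, Rpsa, Bub1, Nol9, Ubfd1 and Ppan. Ncl encodes the nucleolar protein nucleolin, and its peak spanned 86358325 to 86359420 on chromosome 1 with the centre in intron 1. Ddx21, Utp20, Gar1 and Ppan also act in ribosome production, Trmt61a and Mettl1 methylate tRNA, Rrm2 is a subunit of ribonucleotide reductase, Ccne2 is a cyclin and Bub1 a mitotic checkpoint kinase.

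Genes of the cell cycle, protein synthesis, splicing, chromatin, cilia and imprinted loci carried Sap130 promoter peaks more often than other genes. Of 46 cell cycle and DNA replication genes, 42 (91.3%) had a promoter peak (adjusted exact p = 6.19e-09), led by Rrm2, Ccne2, Bub1 and Wee1, the last with a 2620 bp peak at place 21. The 4 exceptions were Ccnd1, Aurka, Orc1 and Orc6, of which Orc1 also had no peak near either gene end. Peaks were labelled for 65 of 75 cytosolic ribosomal protein genes (86.7%, adjusted exact p = 1.30e-10), with Rpsa and Rpl14 earliest. The share was 90% (54 of 60) for mitochondrial ribosomal and respiratory chain proteins (adjusted exact p = 1.69e-10) and 86% (43 of 50) for splicing factors (adjusted exact p = 2.00e-07), led by Srsf1 with a 2377 bp peak at place 94. Of 61 chromatin regulators, 55 (90.2%) carried a peak (adjusted exact p = 1.30e-10), including the SWI/SNF subunit Smarcc1, the acetyltransferases Kat2a and Kat6a, and Kmt2d. Among 44 cilia and ciliopathy genes, 40 (90.9%) did (adjusted exact p = 1.83e-08), including Mks1, Pkd1 and Ift88, while Ift140, Cep290, Cc2d2a and Kif7 had no label. A peak overlapped the 1 kb around an end of Ift140, Cep290 and Kif7. It was labelled with another gene (Cramp1l for Ift140, Tmtc3 for Cep290) or, for Kif7, with none. Cc2d2a had no peak near either end. Imprinted genes were at 90.5% (19 of 21, adjusted exact p = 0.00015), among them Igf2r and Mest, with Igf2 and Rtl1 the exceptions, and lost the call with a window of 500 bp (57.1%, adjusted exact p = 0.34) and among the first 8115 peaks (52.4%, adjusted exact p = 0.086).

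Genes of neural progenitors, neurons and axon growth also carried promoter peaks more often than other genes. The share was 78.6% (22 of 28) for radial glia and neural progenitor markers (adjusted exact p = 0.0025), including Msi1, Notch2, Hes5 and Vim. Sox2 had a peak of 4248 bp and Pax6 one of 2919 bp, 2 genes chosen after their values were seen. It was 75% (27 of 36) for neurogenic and regional transcription factors (adjusted exact p = 0.0026), including Insm1, Pou3f3, Cux1 and Bcl11b, and 73.3% (22 of 30) for neuronal markers (adjusted exact p = 0.011), including Mapt, Tubb3, Grin1 and Elavl4. Axon guidance genes reached 88.6% (39 of 44, adjusted exact p = 1.43e-07), with the semaphorin receptor genes Plxna1 and Plxnb2 earliest and Robo3, Sema3d, Sema3e, Sema3f and Epha7 the exceptions. An unlabelled peak overlapped the 1 kb around an end of Sema3f and of Epha7, while Robo3, Sema3d and Sema3e had no such peak. Notch, Wnt and hedgehog pathway genes reached 78.6% (33 of 42, adjusted exact p = 0.00020), including Ctnnb1, Fzd3 and Dvl1. No peak lay near either end of Neurog1, Neurod4, Tbr1 or Rbfox3.

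Several of these neural lists lost their call in the first part of the list or with a narrower window, while axon guidance genes passed in both (54.5% of genes, adjusted exact p = 0.0053 among the first 8115 peaks, and 68.2%, adjusted exact p = 0.0038 within 500 bp). Among the first 8115 peaks, radial glia and progenitor markers were at 28.6%, neurogenic and regional factors at 27.8% and neuronal markers at 30%, against 33.0% of other genes, and none of these differences passed the test (adjusted exact p = 0.76, 0.70 and 0.87 by Fisher's exact test). The Notch, Wnt and hedgehog genes passed there (50%, adjusted exact p = 0.031). With a window of 500 bp the shares of these 3 lists were 46.4%, 50% and 56.7%, and that of the Notch, Wnt and hedgehog genes 57.1%, against 44.0% of other genes, and none passed (adjusted exact p = 0.89, 0.56, 0.26 and 0.12). For neuronal markers the call also ended with a peak centre within 1 kb of either gene end (73.3%, adjusted exact p = 0.071), but not within 3 kb (96.7%, adjusted exact p = 4.39e-06) or for any overlap with the 1 kb around a gene end (93.3%, adjusted exact p = 1.39e-05). For radial glia and progenitor markers the call held with a peak centre within 3 kb of either gene end (96.4%, adjusted exact p = 1.22e-05). It also held for any overlap with the 1 kb around a gene end (96.4%, adjusted exact p = 4.37e-06). Their call ended with 1 start per gene (53.6%, adjusted exact p = 0.28). Under that setting axon guidance genes fell to 61.4% and Notch, Wnt and hedgehog genes to 61.9%, against 42.4% of other genes. Both still passed (adjusted exact p = 0.019 each). Neurogenic and regional factors (61.1%) and neuronal markers (63.3%) passed as well (adjusted exact p = 0.034 each).

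Autism-associated genes carried promoter peaks more often than other genes, and congenital heart disease genes were not shown to differ from them. The difference between these 2 lists was not tested. A raised share was not particular to the autism list, since splicing factors (86%) and chromatin regulators (90.2%) had higher shares. Some genes, such as Kmt2c, Chd2 and Chd8, are on both the autism and the chromatin list, and promoter CpG content was not taken into account. Of 61 autism-associated genes, 50 (82.0%, interval 70.0 to 90.6) had a promoter peak (adjusted exact p = 4.33e-07). With 1 start per gene the share was 55.7%, against 42.4% of other genes, and passed only narrowly (adjusted exact p = 0.0445). Earliest were the zinc finger factor gene Bcl11a, whose 4496 bp peak stood at place 582, then Kansl1 (3253 bp), Kmt2c and Ankrd11. Ash1l, Chd2 and Chd8 were among the 11 without a label, and for each of these 3 a peak overlapped the 1 kb around a gene end, in the case of Chd8 a 1595 bp peak labelled Supt16 and a 1266 bp peak without a label. Of 40 congenital heart disease genes, 20 (50%, interval 33.8 to 66.2) had a promoter peak, against 49.2% of other genes (adjusted exact p = 1). With a window of 500 bp the share was 30%, against 44.0% of other genes, without passing the test (adjusted exact p = 0.12). Among those with a peak were Kmt2d, Ptpn11 and Crebbp, which act in chromatin or growth factor signalling. The cardiac transcription factor genes Nkx2-5, Gata4 and Gata6 had none.

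**Figure D2:**
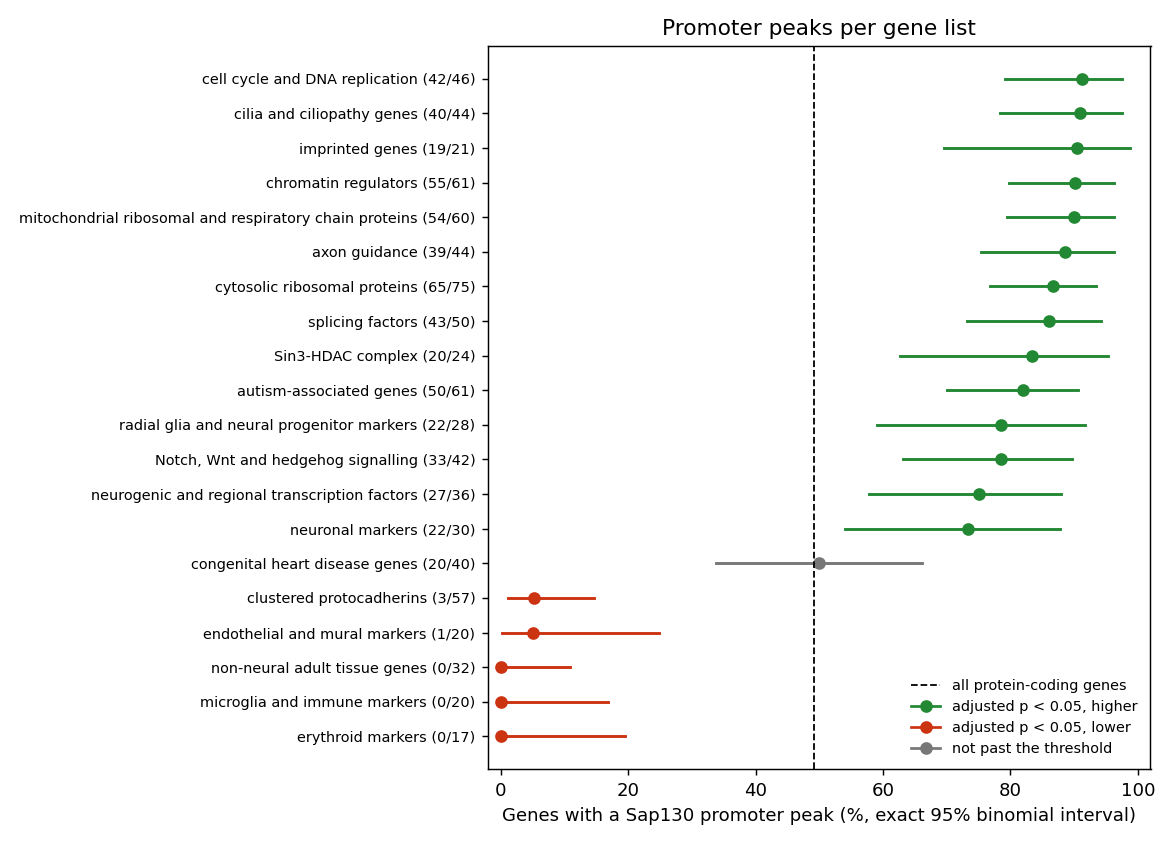
Share of the genes of each fixed list with a Sap130 promoter peak (points, in %) with exact 95% binomial intervals (lines); counts stand beside the names, and the dashed line marks all protein-coding genes (49.2%). Lists of proliferation, chromatin and neural genes lie to the right, congenital heart disease genes lie on the line (50%), and protocadherins and non-neural markers lie to the left.

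Clustered protocadherins, cell adhesion genes that lie side by side on chromosome 18, were nearly free of promoter peaks. Only 3 of 57 genes had one (5.26%, interval 1.1 to 14.6, adjusted exact p = 1.12e-11), namely Pcdhgc3, Pcdhac2 and Pcdhgc4. The test and the interval treat the genes as independent. These genes are neighbours and many overlap, so both can overstate the evidence. Pcdha9 (chromosome 18, 36997880 to 37187657), known from earlier work on the Sap130 mutant mouse, had no peak within 1 kb of either end. The cluster spans 912 kb and contained 8 peaks, of which 1 was labelled Taf7 and 2 had no gene. The genes of this cluster are similar in sequence, and how reads with several matches were treated is not given in the sources used here.

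Markers of blood, vessel and immune cells, which a whole embryonic brain can contain, and genes of adult non-neural organs were almost never labelled. No promoter peak was found for 17 erythroid markers (which allows a share of up to 17.6%), 20 microglia and immune markers (up to 15%) or 32 genes of adult non-neural tissues (up to 9.38%), with adjusted exact p = 2.74e-05, 3.77e-06 and 2.14e-09. These include the globin genes Hba-a1 and Hba-a2, Csf1r and Cx3cr1 of microglia, and Alb and Apoa1 of liver. With a peak centre within 1 kb of either gene end accepted, the adult non-neural genes were at 18.8% (adjusted exact p = 6.99e-05). Of 20 endothelial and mural markers, 1 had a peak, the 235 bp peak of Foxc1 at place 14721 (5%, adjusted exact p = 6.66e-05).

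In place of peak height, the place in the list and the width of promoter peaks were compared between lists. The median place of all protein-coding promoter peaks was 5851.5. Cell cycle genes stood earliest, with a median place of 1575.5 (central 95% of random lists 4133 to 7745). Chromatin regulators (2317), cytosolic ribosomal proteins (2398), Sin3-HDAC genes (2481.5) and splicing factors (2889) also stood earlier than the central 95% of random lists, and these 5 lists did so too against lists matched on width. Neurogenic and regional factors (10697), neuronal markers (8781) and radial glia and progenitor markers (8558) stood later than the range of their random lists, and also later than lists matched on width. Axon guidance (7184), Notch, Wnt and hedgehog (6029) and imprinted genes (7761) lay within the range of random lists but later than lists matched on width (upper ends 6336, 5860 and 7232). Width gave another order. The widest promoter peaks belonged to congenital heart disease genes with a peak (median 1534 bp, random range 623 to 1115 bp) and chromatin regulators (1467 bp). At matched places, peaks of radial glia and progenitor markers (1181 bp) and of axon guidance genes (1106 bp) were among those wider than the central 95% of random lists (543 to 892 bp and 642 to 937 bp). Peaks of neurogenic and regional factors were narrower (565 bp, random range 646 to 1079 bp) but lay within the range at matched places (443 to 740 bp), and those of mitochondrial proteins were narrower at matched places (718.5 bp, range 768 to 1036.5 bp). In all, 15 lists with at least 5 promoter peaks were compared, and these percentiles were not adjusted for that number.

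**Figure D3:**
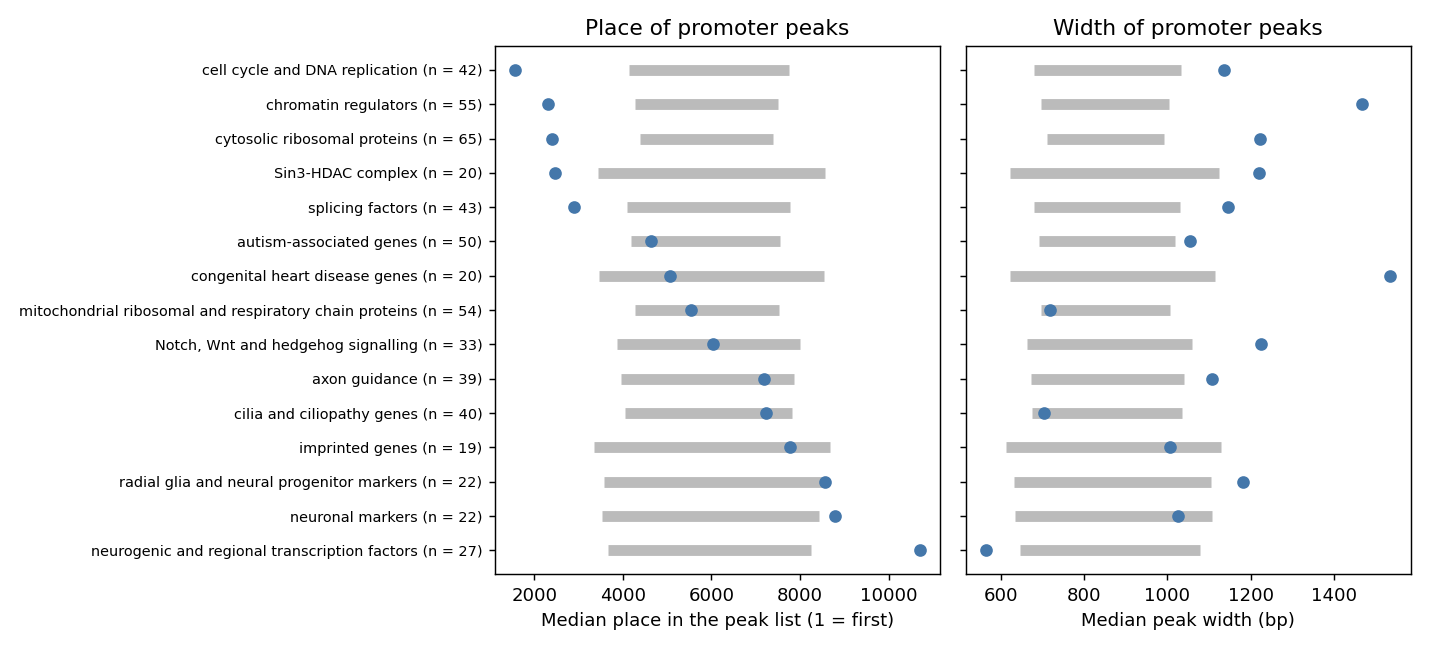
Median place in the peak list (left, 1 is the first peak) and median width in bp (right) of the promoter peaks of each list; grey bars give the central 95% of 10000 random lists of the same size. Cell cycle genes stand earliest (1575.5) and neurogenic and regional transcription factors latest (10697).

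X-linked genes carried promoter peaks less often than autosomal genes. The share was 36.7% (332 of 905, interval 33.5 to 39.9) on X and 49.8% (9982 of 20048) on the autosomes, an odds ratio of 0.58 (Fisher's exact test, p = 9.09e-15). Single autosomes ranged from 38.3% on chromosome 7 (interval 36.1 to 40.5), which overlaps the interval of X, to 60.0% on chromosome 12. Among the first 8115 peaks the odds ratio was 0.24 (exact p = 2.97e-55). The median place of promoter peaks was 9917.5 on X and 5696.5 on the autosomes. The sex of the embryos is not stated in the labels, and whether the kinds of genes on X account for the lower share was not tested.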

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

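The list held 5 peaks on the mitochondrial chromosome, which lies outside the nuclear comparisons. These peaks were flagged because their number exceeded 3, a limit for flagging and not a test. Whether they mark binding of Sap130 was not tested. They stood at places 9046 to 16042, were 934 to 2757 bp wide and covered 53.2% of the annotated length, against 0.514% of the nuclear chromosomes covered by peaks.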

How the results depend on the processing

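Stricter thresholds by q-value or fold enrichment were not run, because the table used here gives neither, and the settings that needed strand or sequence (wider windows around starts, bidirectional promoters, CpG matching, motifs) were not run either. No paired analysis was possible because there is 1 library of each kind. The subsets by place and width, the gene-end rules and the wider background were chosen after seeing the data. The cause of each shift below was not tested beyond what the construction of the subset implies. Taking the first or the widest 8115 peaks leaves 8115 of 16231, and the first 8115 have a median width of 996 bp. The share of peaks at promoters was 63.9% within 500 bp, 91.7% in the first and 87.2% in the widest 8115 peaks, and 70.9% and 84.5% for either gene end within 1 and 3 kb. The ratio of median widths of labelled to unlabelled peaks, 1.73, became 1.95 against distal peaks only. The share of protein-coding genes with a promoter peak, 49.2%, was 44.0% within 500 bp, 42.4% with 1 start per gene, 33.0% in the first and 31.6% in the widest 8115 peaks, 55.1% and 57.4% for either gene end within 1 and 3 kb, 55.8% for any overlap with the 1 kb around a gene end, and 47.7% over all protein-coding genes. The lower share on X kept its direction and passed the test under each of the 7 alternatives run for it (odds ratio 0.24 to 0.57, against 0.58). Of 14 lists above other genes, 8 remained within 500 bp, and the 5 lists below other genes passed under all 8 alternatives. The lists that lost their call within 500 bp were Sin3-HDAC (54.2%), radial glia and progenitors (46.4%), neurogenic and regional factors (50%), neuronal markers (56.7%), Notch, Wnt and hedgehog (57.1%) and imprinted genes (57.1%). With 1 start per gene radial glia and progenitors lost it (53.6%), and with either gene end within 1 kb neuronal markers did (73.3%). In the first 8115 peaks imprinted genes lost it (52.4%), and radial glia and progenitors (28.6%), neurogenic and regional factors (27.8%) and neuronal markers (30%) turned to below other genes without passing the test. In the widest 8115 peaks neurogenic and regional factors did so (30.6%). Without read totals, what depth limits could not be assessed, and a promoter without a peak is only one that was not called.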

Other observations

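The analyses in this part were set after the peak table had been examined. Of the tests, those of the Y-linked homologues and of the unlabelled protocadherins were chosen only after their results were seen. Among unlabelled nuclear peaks, 2458 lay over 1 kb from the ends of curated genes and are called distal. Of these, 68.0% lay inside protein-coding genes, and their median width was 390.5 bp. Distal does not mean far from a gene: of 3570 unlabelled nuclear peaks, 2006 had their centre within 3 kb of a gene end. Only 1112 overlapped the 1 kb around one. Genes of neural development had such distal peaks within 50 kb more often than random genes of matched length. The share was 60.7% (17 of 28) for radial glia and progenitor markers, 58.3% (21 of 36) for neurogenic and regional factors, 57.1% (24 of 42) for Notch, Wnt and hedgehog genes, 52.5% (32 of 61) for autism-associated genes and 52.3% (23 of 44) for axon guidance genes. Length-matched random lists had medians of 17.9% to 21.3% for these 5 lists, with an upper end of the central 95% of at most 34.1%. The random lists were not matched on having a promoter peak, so sites beside a promoter were not told apart from sites further away. Chromatin regulators (50.8%), neuronal markers (50%), imprinted genes (47.6%) and cytosolic ribosomal proteins (26.7%, random range up to 25.3%) also lay above their random ranges. Congenital heart disease genes (30%, upper end 30%), erythroid markers (29.4%, upper end 29.4%) and cell cycle genes (28.3%, upper end 30.4%) lay at or near the upper end of theirs. Cilia genes (11.4%), mitochondrial proteins (11.7%) and splicing factors (20%) stayed within the random range, and non-neural adult tissue genes had none of 32. The clustered protocadherins (63.2%) share the same few peaks, so that their genes are not independent. Btn2a2 had the most distal peaks within 50 kb (14), followed by Bcor (13), a corepressor gene, and by Lhx2, Meis2 and Tcf4 (12 each), which encode transcription factors. Btn2a2 and the 3 genes with 11 (Abt1, Btn1a1 and Trim27) lie in the tRNA gene region of chromosome 13, and Fam172a, Nfib, Nr2f1 and Sox2 had 10. These counts include peaks inside the gene and were not matched on gene length, and neighbouring genes can share the same peaks. The 10 distal peaks earliest in the list had Foxk1, Arid1a, Smim17, Hmgb1, Foxo3, Midn, Zfp423, Btbd19, Kmt5a and Sox11 as nearest protein-coding genes, the first being a 944 bp peak 33888 bp from Foxk1 (chromosome 5, 142367137 to 142368081, place 59). The widest distal peak was 6169 bp long (chromosome 13, 83727335 to 83733504), with Mef2c as the nearest protein-coding gene at 63340.5 bp, and the next lay within Rhof (5284 bp), Tnrc18 (4993 and 4430 bp), Midn (4377 bp), Meis2 (4368 bp) and Auts2 (4314 bp). The genes with the most and the widest distal peaks were chosen after their values were seen. The 20 lists were not adjusted for their number.

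Distal peaks also gathered at tRNA genes, which RNA polymerase III transcribes. A tRNA gene lay within 1 kb of 101 of 2458 distal peaks (4.11%), against at most 0.203% in 100 random placements, and 36 of the 101 fell between 21159856 and 23519619 on chromosome 13. Counting all peaks, 85 of 408 tRNA genes (20.8%) were overlapped. If reads of multi-copy small RNA genes had given these peaks, predicted snRNA loci should carry them too, but only 9 of 1003 (0.897%) did. Most snRNA loci are predicted and make an imperfect control, since they may be less alike or less transcribed than tRNA genes. The result therefore does not decide the source. Sap130 signal at tRNA genes stays a hypothesis, since signal that any antibody may give at strongly transcribed loci was not tested.

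Promoter peaks of X-linked genes stood late in the list. If the kinds of genes on X were the reason, X-linked members of the fixed lists should stand with the autosomal members of the same lists. Instead the 22 X-linked members had a median place of 8285, the 99.6th percentile of 10000 list-matched random sets (central 95% 2813 to 7489), which argues against gene content as the whole reason. A single X copy in male cells of the sample could not be decided. None (0 of 4) of the Y-linked homologues Ddx3y, Eif2s3y, Kdm5d and Uty had a peak although their 4 X-linked counterparts did, but whether Y was kept in peak calling is not known, and an inactive X in female cells was not tested.

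Many genes without a label may owe this to how genes were joined to peaks, since each peak carried 1 gene and its centre had to lie within 1 kb of the start. Of 105 unlabelled members of the brain, disease and housekeeping lists without the clustered protocadherins, 62 (59.0%) had a peak overlapping the 1 kb around a gene end, compared with 8 of 88 unlabelled non-neural genes (9.09%, Fisher's exact test, p = 1.01e-13). The non-neural lists had few peaks under every setting, so this contrast cannot tell the joining rule from a general lack of peaks. For 40 of the 62 such a peak was labelled with another gene, as for Aurka (Cstf1). For 10 of the 62 an unlabelled peak had its centre within 1 kb of the gene end, and for 5 of these no other kind of peak was found, which the joining rule leaves open. The joining rule cannot account for the 54 unlabelled protocadherins, of which 0 had such a peak, and with them the share was 39.0% (62 of 159). Of 222 unlabelled nuclear peaks of 2 kb or more, 163 (73.4%) overlapped such a window, against at most 11.7% in random placements, and only 23 of the 163 had their centre within 1 kb of the gene end. Over unlabelled peaks of any width, however, 726 of the 1112 that overlapped such a window had their centre within 1 kb of the gene end, which the centre rule leaves open, since without strand these can be 3′ ends or starts that the authors' models lack.

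Because nucleolar genes were seen at the head of the list, a hypothesis was that genes of this kind stand early as a group. It was tested on 50 nucleolar and ribosome biogenesis genes chosen from outside the first peaks that had been viewed. Of these, 40 had a promoter peak, with a median place of 667, while the central 95% of width-matched random lists ran from 3178 to 6062. The percentile was 0, as none of 10000 random lists stood as early, so the early place of genes of this kind extended beyond the members already seen. The earliest, chosen after their values were seen, were Ebna1bp2 (place 66), Gnl3 (67) and Npm1 (71). Since the quantity that orders the list is not stated, an early place may reflect peak significance or height, and this was not tested. Input DNA was the only control, so signal that any antibody may give at strongly transcribed loci was not tested here either.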
